A study of Arabidopsis thaliana with 36 samples.

How the data were processed

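Rosette leaves of Arabidopsis thaliana Col-0 were sampled at 21 and 35 days after sowing (DAS), at ZT1, 5, 9, 13, 17 and 21, with ZT the hours since lights on. Plants grew under 16 h of light and 8 h of dark at 22 °C and 100 µmol m−2 s−1. Each of the 12 combinations of age and time has 3 libraries of polyadenylated RNA, which makes 36 libraries. The labels name the 3rd and 4th rosette leaves, and the series text names the third leaf. Sample titles number the 3 libraries of a group as batches 1 to 3, while the series text calls them biological replicates.

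The deposited table holds FPKM (fragments scaled to transcript length and to the total of the library) for each transcript and library. Per the submitters' processing notes, reads were aligned to TAIR10 with STAR 2.3.0e, counted with HTSeq and processed with edgeR 3.12.1. The step that turned counts into FPKM is not described. The table lists 41342 transcripts of 33279 loci on chromosomes 1 to 5, beside 36 unnamed columns that hold no values. One of its columns counts samples up to 72, so it may have been taken from a larger table. Positions of the loci were checked against the TAIR10.1 annotation, where 100% of the 32803 loci compared overlapped the locus with the same identifier.

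FPKM of the transcripts of a locus were summed, and loci are called genes below. Genes with 1 FPKM or more in at least 3 libraries were kept, which left 18729. Values were analysed as log2(FPKM + 1). Because 1 is added, changes of genes near 0 FPKM at either age are compressed and depend on that addend. limma 3.58.1 in R 4.3.3 fitted the 12 group means together, with eBayes and a mean-variance trend, so that all groups share 1 estimate of the spread. Contrasts were the age effect (35 minus 21 DAS) averaged over the 6 times, the age effect at each time, and the age effect at night (ZT17 and ZT21) minus that by day (ZT1, 5, 9 and 13). A daily rhythm was fitted to the 6 means of each age as a 24-h cosine and sine. A gene was called rhythmic when the F test passed and the fitted amplitude was at least 0.5, which is a peak-to-trough change of at least 1 log2 unit. The rhythm difference between ages was its own F test on the cosine and sine terms. Calls used a Benjamini-Hochberg adjusted p under 0.05.

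Shares of genes peaking in the dark (ZT16 to ZT24), shifts of peak time and ratios of amplitude have no test across genes, since genes are not replicates. Their error is the SD over the 3 replicate numbers, each taken as 1 series of 6 times. A night-pattern score was computed for each library. It is the mean standardised level of genes peaking at ZT16 to ZT24 at 21 DAS minus that of genes peaking at ZT4 to ZT12 at 21 DAS. The genes were chosen at 21 DAS, so the daily swing of the score is larger at 21 DAS by construction. An apparent time of day was estimated for each library from the fitted 21 DAS profiles of the other replicate numbers. Both were compared between ages by a two-sided permutation test that moved ages within each time, with 100000 permutations.

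There were 27 gene lists with 480 members, of which 454 were tested. Their age and night-minus-day effects were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 27 lists. The plan also named fry, which tests whether the members of a list change at all. For the age effect, a shift of all genes can pass it. With fry, reference genes were called higher as deposited and lower after rescaling (adjusted p = 7.11e-13 and 7.04e-09). Calls of fry are therefore given for night minus day alone. The comparisons, the lists, the tests and most alternatives were chosen before the data were examined. Named genes followed a rule from the same stage. For the age effect it takes the 10 highest and 10 lowest log2 fold changes among called genes with a mean of 5 FPKM or more and 1 sign at all 6 times. For each time it takes the 2 highest and 2 lowest called genes. For the night-minus-day contrast it takes the 6 highest and 6 lowest called genes, and for the rhythm difference the 12 with the smallest p. For rhythm it takes the 6 largest amplitudes at each age. For peak time it takes the 5 largest advances and 5 largest delays among genes rhythmic at both ages with an amplitude of at least 1 at both. Members of the fixed lists are named beside their list.

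Depth is not stated in the table. In single-transcript genes with low values, 86% of 5193 FPKM values lay within 10% of a whole number of steps of 1 size per gene and library, against 37.5% if they were even. These steps give a median of 22 fragments per unit of FPKM, and depths relative to the middle library of 0.768 to 1.85. Absolute depth and counting intervals were not computed from them. Sums of FPKM per library ran from 829518 to 952310.

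Batch numbers were checked as pairs. The deviations of libraries from their group means had a mean correlation of 0.00856 within a number, with pairs from −0.473 to 0.582, and −0.00445 between numbers. Deviations of a group sum to 0, so the mean between numbers is nearly fixed by that within. As the mean within a number was near 0, the numbers entered only as a block in an alternative. Alternatives were an addend of 0.1, no filter on low values, median-of-ratios rescaling of each library, array weights, the replicate block, other definitions of rhythm, and leaving out each library and each replicate number. Alternatives added after the data were seen were other dark boundaries (that at ZT14 also with rescaling), genes rhythmic at both ages, each age fitted alone, and 5 doubted libraries left out together. These 5 are the 4 with reads at AT2G01021, which is at 0 in all others, and those farthest from their group means, with 1 library in both sets.

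The procedures were tested on simulated data with the same 36 libraries and 18729 genes, and with the spread of each age. Of genes simulated with age effects of 0.5, 1 and 2 log2 units, 97.0%, 97.0% and 100% were recovered, and 3.92% of calls were false. Rhythmic genes simulated with an amplitude of 1 were recovered at 99% and 98% at 21 and 35 DAS, with 4 and 51 false calls. Recovery nearer the amplitude minimum of 0.5 was not simulated. Changed genes were drawn from those with a mean log2 value above 2, and noise was independent between genes. Of genes with a simulated rhythm difference, 83.6% were recovered, and 6.49% of those calls were false. A simulated delay of 2 h was estimated as 1.95 h. With no age difference simulated, the night-pattern score had a permutation p of 0.420. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The sum over transcripts leaves out any change in the use of isoforms. Genes below the filter were left out of all main tests.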

Results

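Transcript levels were measured by RNA sequencing in rosette leaves of Arabidopsis thaliana Col-0, at 21 and 35 DAS and at 6 times of day. The lights were on from ZT0 to ZT16, so ZT17 and ZT21 were in the dark. Each of the 12 groups has 3 libraries. The depth of each library is not stated in the table, and the sum of FPKM ran from 872504 to 952310 at 21 DAS and from 829518 to 947688 at 35 DAS. A library had between 16113 and 17131 genes at 1 FPKM or more. The series title names a move of daily expression toward the night pattern in aged plants, which is the question the comparisons between ages address.

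Age separated the libraries on the first principal component, with 48.2% of the variance, and the time of day spread them on the second, with 13.6%. Libraries of 35 DAS differed more within their groups. The SD of the deviation of a library from its group mean was 0.193 ± 0.0221 (SD, n = 18) at 21 DAS and 0.300 ± 0.0681 (SD, n = 18) at 35 DAS (permutation test of ages within times, p = 1e-05, the smallest that 100000 permutations can give). Libraries of a group are measured from 1 shared mean, so their deviations are not independent and this p overstates the evidence. Within-group correlations had a median of 0.988 at 21 DAS and 0.972 at 35 DAS. The locus AT2G01021 was at 0 FPKM in all but 4 libraries, which held 74543 FPKM at 21 DAS ZT17 and up to 36327 FPKM at 35 DAS.

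**Figure D1:**
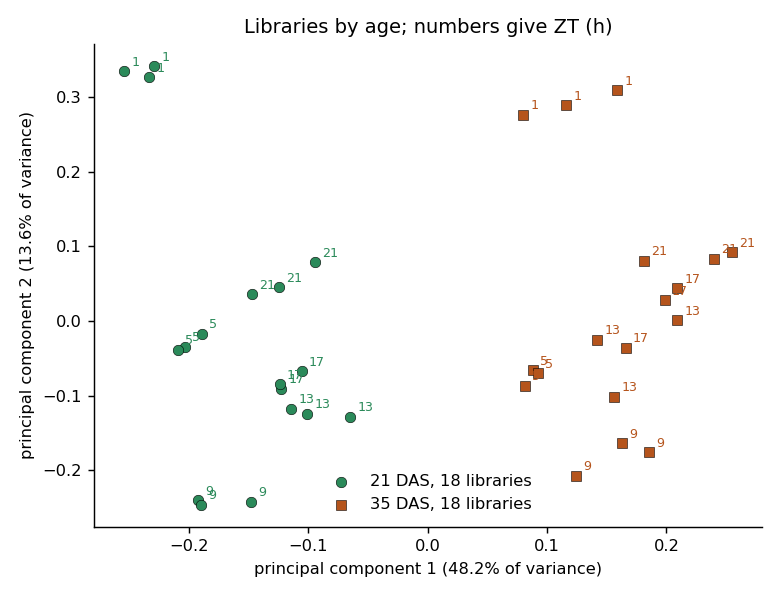
Principal components 1 and 2 of log2(FPKM + 1), unitless, with their percent of the variance. Each point is 1 of 36 libraries, coloured by age, and the number beside it gives its ZT in hours. The 18 libraries of each age lie on opposite sides of 0 on component 1, and ZT1 lies highest on component 2 at both ages.

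Between 21 and 35 DAS, AT2G10940, of the lipid transfer protein superfamily (TAIR10, chromosome 2, 4310412 to 4312103), fell from a mean of 901 to 0.678 FPKM, a log2 fold change of −8.96 ± 0.16 (SE, 18 libraries per age). TGG2, a myrosinase that cleaves glucosinolates (chromosome 5, 9072727 to 9075690), fell by 6.24 ± 0.15 on the log2 scale. AHP4, a phosphotransfer protein of the cytokinin relay (chromosome 3, 5554258 to 5555603), rose from 0.330 to 69.4 FPKM, a log2 fold change of 5.69 ± 0.10. HIS1-3, a linker histone known for induction by drought (chromosome 2, 7845923 to 7846884), rose by 5.38 ± 0.12.

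The other genes with the largest falls were AT3G16670 (−5.88), the arabinogalactan proteins AGP21 (−5.78) and AGP17 (−5.09), the vacuolar aquaporin DELTA-TIP (−5.36), the germin-like protein GER3 (−5.34), the thionin gene AT1G66100 (−4.92), the expansin EXPA8 (−4.80) and DGR2 (−4.75). The other largest rises were those of the metallothionein MT1A (8.36), AT5G39520 (6.02), the calmodulin-like CML41 (5.48), the vacuolar cation exchanger CAX3 (5.37), AT4G01390 (4.97), TAR4 (4.90), DR4 (4.78) and AT3G22600 (4.74). MT1A was close to 0 at 21 DAS, with a mean of 0.00301 FPKM, and uneven between libraries of 35 DAS (SE 0.73). DELTA-TIP, DGR2, MT1A and AT5G39520 each overlap another annotated locus.

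Genes of the photosynthetic apparatus fell together. All 27 measured genes of photosystems and electron transport fell, with a median of −1.33, among them PSBQ1 (−2.28 ± 0.09) of photosystem II and PSAD1 (−1.75 ± 0.07) of photosystem I. All 20 Calvin cycle genes fell (median −1.12), among them the Rubisco small subunits RBCS2B (−3.14 ± 0.19) and RBCS1A (−2.10 ± 0.11). Of 21 light-harvesting antenna genes, 20 fell (median −1.47), with LHCB1.4 at −3.90 ± 0.25 and LHCB2.3 at −3.88 ± 0.12. LHCB7 rose by 0.34 ± 0.06 but was not called after rescaling, at −0.06. Of 20 chlorophyll synthesis genes, 18 fell and 2 rose, with DVR at −2.68 ± 0.15, HEMA1, of the first committed step, at −1.89 ± 0.07, and the regulator GLK1 at 0.68 ± 0.08. Adjusted over the list alone, the counts of these 4 lists were the same. With the preset correlation, camera called each of them lower. With an estimated correlation no list passed, and the adjusted p was 0.0840 for photosystems, 0.146 for Calvin cycle, 0.0840 for antenna and 0.0678 for chlorophyll synthesis, each with an estimated correlation.

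Genes of growth and of some cell types fell as well. Of 21 cell proliferation genes, 19 fell and 2 were not called (median −0.83), with the cyclin CYCD3;1 at −1.51 ± 0.07, the ribonucleotide reductase TSO2 at −1.51 ± 0.13 and the kinase CDKB2;1 at −1.42 ± 0.09 (adjusted p = 0.0678 with an estimated correlation). All 8 xylem markers fell (median −1.57), led by the peptidases XCP2 (−2.84 ± 0.16) and XCP1 (−2.63 ± 0.10) and the laccase LAC4 (−2.08 ± 0.11), with an adjusted p of 0.0840 with an estimated correlation. Of 7 epidermis and trichome markers, 5 fell, among them the lipid transfer protein LTP1 (−3.38 ± 0.18) and CER1, of wax synthesis (−2.50 ± 0.12), with an adjusted p of 0.0840 with an estimated correlation. Of 9 guard cell markers, 7 fell and 1 rose, with GC1 at −2.20 ± 0.26 (adjusted p = 0.0678 with an estimated correlation). Of 10 cytokinin genes, 7 fell and 2 rose (adjusted p = 0.0678 with an estimated correlation). The fallen ones include the feedback regulators ARR6 (−3.45 ± 0.14) and ARR7 (−2.82 ± 0.13), and the risen ones are CRF6 (2.27 ± 0.10) and the receptor AHK3 (0.84 ± 0.05). Adjusted over the list alone, these 5 counts were the same.

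Genes of senescence and recycling rose. All 27 senescence-associated genes rose (median 2.09), including SAG13 (4.46 ± 0.32), the NAC factors ORE1 (3.68 ± 0.17) and NAP (3.15 ± 0.23), which promote leaf senescence, and ORS1 (3.22 ± 0.20). The adjusted p of this list was 0.318 with an estimated correlation. Of 24 autophagy genes, 23 rose (median 0.86), with ATG8B at 2.25 ± 0.09 and ATG8A at 2.01 ± 0.09, and after rescaling 20 rose and 1 fell (adjusted p = 0.326 with an estimated correlation). Of 25 abscisic acid and dehydration genes, 22 rose and 2 fell (median 0.99), with ATHB7 at 2.75 ± 0.13, RD22 at −1.79 ± 0.14 and CYP707A3, which degrades abscisic acid, at −0.54 ± 0.08 (adjusted p = 0.640 with an estimated correlation). Of 12 chlorophyll breakdown genes, 9 rose and 1 fell, with the Mg-dechelatase NYE1 at 1.97 ± 0.12 and the chlorophyllase CLH2 at 1.23 ± 0.10, and after rescaling 7 rose and 3 fell. Camera did not call this list, with an adjusted p of 0.185. Adjusted over the list alone, the counts of these 4 lists were the same.

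Defence and pigment genes rose unevenly between libraries of 35 DAS. Of 22 salicylic acid and defence genes, 21 rose (median 1.66), with the secreted proteins PR1 at 4.53 ± 0.66 and PR2 at 3.38 ± 0.40. The mean level of this list per library ran from 1.87 to 4.39 at 21 DAS and from 2.70 to 6.77 at 35 DAS, in log2 units. Camera called this list only after rescaling, with an adjusted p of 0.00517 there, 0.553 there with an estimated correlation, and 0.185 before. Of 16 flavonoid and anthocyanin genes, 11 rose and 2 fell, with a median of 1.38 and a mean of 1.54, while camera gave the direction as lower before rescaling and higher after, without a call in either. The activator PAP1 rose by 4.53 ± 0.24, the transport protein TT19 by 4.24 ± 0.54 and the enzyme DFR by 3.31 ± 0.59, while the flavonol genes FLS1 and MYB111 fell by 1.91 ± 0.12 and 1.32 ± 0.10. The list mean ran from 1.14 to 2.74 at 21 DAS and from 1.24 to 6.77 at 35 DAS.

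Among hormone and timing lists without a camera call, 19 of 26 jasmonate genes rose and 1 fell, JAZ3, with ORA59 at 2.92 ± 0.18, AOC1 at 2.44 ± 0.11 and MYC2 at 1.69 ± 0.09. Of 8 ethylene genes, 7 rose and 1 fell, with EIN3 at 1.01 ± 0.05. Of 14 flowering time genes, 10 rose and 2 fell, with TSF at 1.99 ± 0.15, FUL at 1.53 ± 0.08, SOC1 at 1.29 ± 0.06 and the repressor FLC at −0.77 ± 0.15. Of 27 circadian clock genes, 22 rose and 3 fell, and after rescaling 16 rose and 6 fell. LNK1 (1.80 ± 0.13) and CCA1 (1.44 ± 0.14) were among the risen ones, and CHE (−1.65 ± 0.11) and RVE2 (−0.55 ± 0.11) fell. Of 11 clock output genes, 10 rose, with the flowering repressor CDF2 at 1.57 ± 0.08 and the growth factor PIF4 at 1.55 ± 0.11. Camera called this list after rescaling, with an adjusted p of 0.0191 there, 0.244 there with an estimated correlation, and 0.0722 before.

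In 5 lists the direction depended on the scaling. Reference genes were 7 up and 0 down, but 1 up and 6 down after rescaling, with UBQ10 at 0.90 ± 0.06. Phloem markers were 5 up and 4 down, but 1 up and 5 down after rescaling, with SWEET12 at 0.73 ± 0.10 and SULTR2;1 at −0.90 ± 0.07. Glucosinolate genes were 10 up and 6 down, but 4 up and 12 down after rescaling, with MAM3 at 1.67 ± 0.16 and MYB34 at −1.32 ± 0.08. Carbon starvation genes were 7 up and 6 down, but 3 up and 9 down after rescaling, with BCAT2 at 4.42 ± 0.13 and DIN10 at −1.38 ± 0.15, and adjusted over the list alone they were 7 up and 5 down. Nitrogen genes were 6 up and 5 down, but 6 up and 8 down after rescaling. The cytosolic glutamine synthetases GLN1;4 (2.68 ± 0.26) and GLN1;1 (2.56 ± 0.20) rose, and ASN2 (−2.33 ± 0.15) and the nitrite reductase NIR1 (−1.42 ± 0.10) fell. Starch genes did not turn, with 10 up and 12 down, and 5 up and 20 down after rescaling, with GBSS1 at 1.57 ± 0.15 and PGM at −1.19 ± 0.08 (camera lower, adjusted p = 0.0170, and 0.624 with an estimated correlation). Median signs turned with rescaling in reference genes, phloem markers, glucosinolate, carbon starvation and nitrogen genes. Besides flavonoid and anthocyanin genes, the median was positive and camera pointed lower before rescaling for phloem markers, glucosinolate, carbon starvation, nitrogen and flower genes. The 2 flower markers split, 1 up and 1 down.

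**Figure D2:**
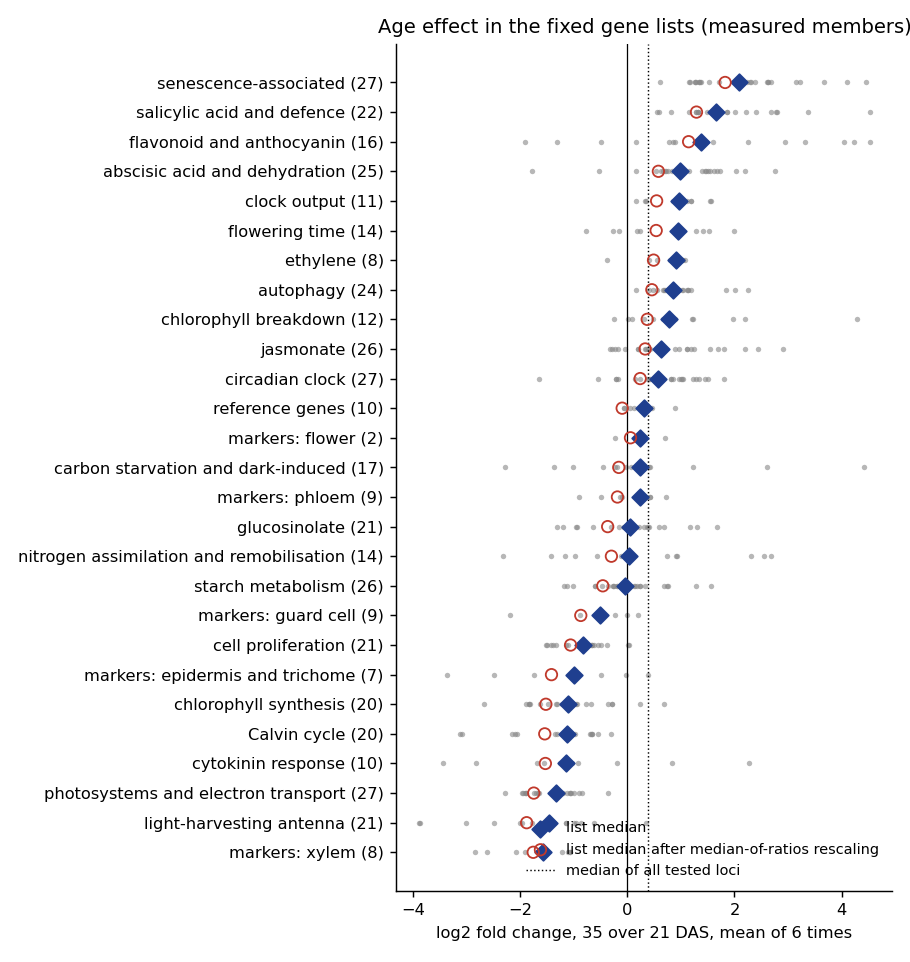
Age effect (x axis, log2 fold change of 35 over 21 DAS, mean of 6 times) in the 27 fixed lists (y axis, with measured members). Grey points are genes, diamonds are list medians from −1.57 to 2.09, open circles are medians after rescaling, and the dotted line is the median of all genes at 0.39. Medians of reference genes, phloem markers, glucosinolate, carbon starvation and nitrogen genes lie on the other side of 0 after rescaling.

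The age effect was called in 16433 of 18729 genes, 12084 higher and 4349 lower at 35 DAS (limma). The median of all genes was 0.39 higher at 35 DAS, and this shift applies to all folds given here. After median-of-ratios rescaling it was 0.04, and 7955 genes were higher and 7199 lower. Of called genes, 12304 had the same sign after rescaling, 1089 turned from higher to lower, and 3040 of the higher ones were no longer called. The fold was at least 2 for 2725 higher and 1302 lower genes, and 9510 higher and 3152 lower genes had 1 sign at all 6 times.

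At single times, AT2G10940 had the largest fall at each of the 6, from −7.08 ± 0.40 at ZT13 to −10.65 ± 0.40 at ZT1 (SE, 3 libraries per age). DELTA-TIP came next at ZT1 (−7.28 ± 0.28), EXPA8 at ZT9 (−7.49 ± 0.47), GER3 at ZT13 (−6.65 ± 0.52), and TGG2 at ZT5, ZT17 and ZT21, with −6.83 ± 0.36 at ZT21. MT1A had the largest rise at all times but ZT5, with 10.21 ± 1.80 at ZT9. The other largest rises were those of AT5G66053 at ZT1 (6.21 ± 1.29) and ZT5 (6.86 ± 1.29), CAX3 at ZT5 (6.41 ± 0.52), DIP2 at ZT9 (6.75 ± 0.56), the noncoding AT1G31258 at ZT13 (6.65 ± 2.24), TT19 at ZT17 (6.63 ± 1.33) and AT5G39520 at ZT21 (6.67 ± 0.55). AT5G66053 lies within AT5G66052. The call of AT1G31258 at ZT13 was lost without replicate 2 and without replicate 3. That of MT1A at ZT17 was lost without replicate 1 and without replicate 2.

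The number of genes called was 13195 at ZT1, 11891 at ZT5, 13086 at ZT9, 10798 at ZT13, 12062 at ZT17 and 13366 at ZT21 (limma). The share higher at 35 DAS was 75.5%, 76.1%, 74.7%, 68.8%, 71.3% and 74.2% in the same order, and after rescaling 48.8%, 47.3%, 48.5%, 50.1%, 49.1% and 48.7%.

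The age effect differed between night and day in single genes such as PIF4 and NIA1. PIF4, a growth-promoting bHLH factor (chromosome 2, 17886427 to 17889050), rose by 3.02 and 3.24 log2 units at ZT17 and ZT21 and by 1.69 and 0.93 at ZT1 and ZT13, and was not called at ZT5 (0.28) and ZT9 (0.14). Its night-minus-day difference was 2.37 ± 0.24 (SE, limma, adjusted p = 3.39e-07). The nitrate reductase NIA1 (chromosome 1, 29235803 to 29239445) was at −1.37 and −3.22 at ZT17 and ZT21. By day it was at −1.12 at ZT1, −0.13 (not called) at ZT5, 1.73 at ZT9 and 0.71 at ZT13, a difference of −2.59 ± 0.26 (adjusted p = 3.2e-07). The BTB scaffold genes BT1 (−3.23 ± 0.25) and BT2 (−3.19 ± 0.38), the latter responsive to nitrate and sugar, also had lower age effects at night. Others with lower effects at night were AT5G66053 (−4.94 ± 1.11), AT3G28220 (−3.24 ± 0.47) and AT4G29905 (−2.47 ± 0.41). Effects were higher at night for ELIP1, an early light-induced protein (2.27 ± 0.53), STO, a B-box factor (1.86 ± 0.18), the galactinol synthase GolS2 (1.78 ± 0.29), LNK2 (1.77 ± 0.26) and CDF2 (1.76 ± 0.17). The call of ELIP1 was lost without replicate 2, and that of AT5G66053 without replicate 3.

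By list, 11 of 26 jasmonate genes had a lower age effect at night and 0 a higher one (13 lower adjusted over the list alone), with CORI3 at −1.99, LOX2 at −1.78 and AOC2, of jasmonate synthesis, at −1.47. Of 27 photosystem genes, 14 were lower at night and 0 higher (19 lower adjusted over the list alone, and 10 after rescaling), with PSAD1 at −1.24 and PSBX at −1.03. Of 21 antenna genes, 10 were lower and 1 higher (also adjusted over the list alone), with LHCB6 at −1.05 among the lower ones and LHCB2.3 the higher one. Of 10 cytokinin genes, 5 were lower (5 lower and 1 higher adjusted over the list alone), with ARR7 at −2.25, ARR6 at −1.82 and ARR4 at −1.61. Of 11 clock output genes, 6 were higher and 1 lower (6 and 2 adjusted over the list alone), with CDF3 at 1.25. Camera called these 5 lists and, before rescaling alone, Calvin cycle genes (2 lower, 0 adjusted over the list alone) and ethylene genes (2 higher, 3 adjusted over the list alone). The adjusted p with an estimated correlation was 0.212 for jasmonate, cytokinin and clock output, 0.542 for photosystems, 0.628 for antenna, 0.869 for Calvin cycle and 0.613 for ethylene. With fry it was 2.9e-05 for cytokinin, 6.38e-05 for clock output, 0.000137 for jasmonate and 0.00509 for photosystems. It was 0.03745 for antenna, 0.03749 for ethylene and 0.315 for Calvin cycle with fry, and 0.0704 for antenna after rescaling.

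Of lists that camera did not call, 4 of 14 nitrogen genes were lower at night and 2 higher (7 lower and 3 higher adjusted over the list alone), with NIA2 at −1.27 and NIR1 at −1.10. With fry the nitrogen list passed as lower (adjusted p = 6.16e-05), and guard cell markers passed as higher (adjusted p = 0.0219). Of 27 clock genes, 4 were higher and 2 lower (6 and 5 adjusted over the list alone), with LNK1 at 1.35, PRR7 at 0.97 and CHE at −1.22. The calls of LNK1 and PRR7 were lost without replicate 1, and that of CHE without replicate 3. Of 14 flowering time genes, 1 was lower and 1 higher, the florigen gene FT at −1.68 and the repressor SVP at 0.51 (also adjusted over the list alone). Of 22 salicylic acid and defence genes and 12 chlorophyll breakdown genes, 0 differed, and adjusted over the list alone also 0 (limma).

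The contrast was called in 2952 genes, 1210 with a higher and 1742 with a lower age effect at night (limma), and in 1401 and 1732 after rescaling. Leaving out 1 replicate number gave between 1165 and 1308 genes, with 2 libraries per group.

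**Figure D3:**
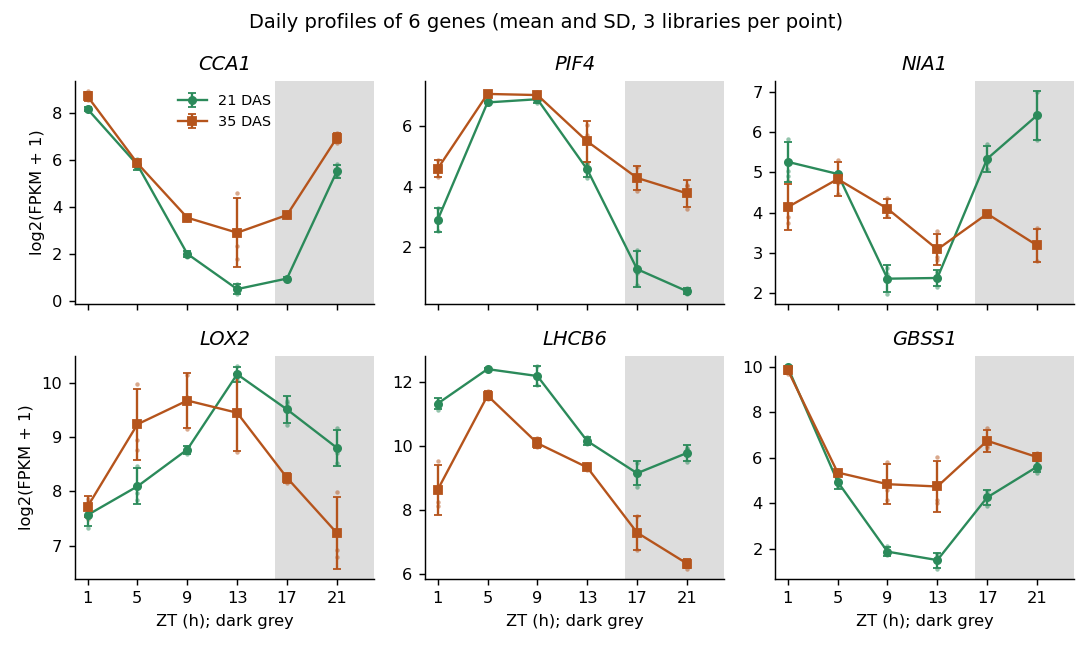
Daily profiles of CCA1, PIF4, NIA1, LOX2, LHCB6 and GBSS1 (x axis, ZT in hours, dark in grey, y axis, log2(FPKM + 1)) at both ages. Large points are means with SD of 3 libraries and small points are libraries. PIF4 was higher at 35 DAS by 3.24 at ZT21 and NIA1 was at −3.22, and the peak of LOX2 came 4.75 h earlier.

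At 21 DAS the largest fitted amplitudes were those of AT5G66053 (4.64), the clock factor LHY (4.50), BT2 (4.36), LHCB2.2 (4.24), LHCB1.1 (4.18) and the clock-related RVE2. At 35 DAS they were those of LHCB1.1 (4.03), LHCB2.2 (3.90), RVE2 (3.78), LHCB2.1 (3.68), LHY (3.65) and LHCB1.2 (3.53). Of 27 clock genes, 24 were rhythmic at 21 DAS and 23 at 35 DAS, and the median amplitude was 2.85 and 2.07, lower at 35 DAS in 23 of 27. CCA1, a morning factor of the clock (chromosome 2, 19245672 to 19248914), had amplitudes of 3.96 and 2.88 ± 0.14 (SE), PRR7 had 3.27 and 2.32 ± 0.09, and PRR9 had 2.90 and 2.92 ± 0.18.

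At 21 DAS 5016 genes were rhythmic and at 35 DAS 3249 (limma), and after rescaling 4396 and 2869. Of these 2398 were rhythmic at both ages, against 870 if independent. A gene called at 1 age alone is not thereby shown to differ, and the rhythm difference has its own test.

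Genes with the clearest rhythm differences mostly had lower amplitudes at 35 DAS. The pectinesterase PME53 dropped by 1.54 to an amplitude of 0.16 ± 0.06 (SE, limma, adjusted p = 1.31e-11), and AT1G60590, of the pectin lyase superfamily, from 1.88 to 0.02 ± 0.08. These 2 genes were near 0 at 35 DAS, with means of 0.240 and 0.0385 FPKM, where log2(FPKM + 1) cannot show an amplitude, so their difference is not separate from their fall with age. AT5G23240, with a DnaJ domain, went from 3.65 to 2.38, AT1G13650 from 2.62 to 0.98, AT1G55960 from 2.39 to 1.02, RUP2, a repressor of UV-B signalling, from 2.03 to 0.99, and AT5G43440 from 1.98 to 1.27. HDR, the last enzyme of the plastid isoprenoid pathway, went from 1.49 to 0.79, and AT3G01310 from 1.33 to 0.70. The amplitude of MAP1C, a methionine aminopeptidase, was 0.81 and 0.85, and its peak came 3.07 ± 0.23 h earlier. NIA1 and BT1 had amplitudes of 2.02 and 1.57 at 21 DAS and 0.61 and 0.94 at 35 DAS, with peaks at ZT22.4 and ZT21.1 against ZT4.7 and ZT4.2. PIF4 went from 3.50 to 1.78 ± 0.11 and the starch synthase GBSS1 from 3.67 to 1.83 ± 0.15. In all, 5073 genes differed, of which 2859 were called rhythmic at 1 age or more and 961 at both ages. The other genes that differed were called rhythmic at neither age. Leaving out 1 replicate number gave between 1922 and 2673 genes, with 2 libraries per group.

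Among genes rhythmic at both ages, 1659 had a lower and 739 a higher amplitude at 35 DAS. The median log2 ratio was −0.21, and −0.21 ± 0.06 over replicate numbers (SD, n = 3). Photosystem genes went the other way, with a higher amplitude at 35 DAS in all but 3 of 27 and a median log2 ratio of 0.42 ± 0.16 (SD, n = 3) over the 16 rhythmic at both ages.

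Shifts of peak time went mostly earlier in jasmonate, starch and dehydration genes and mostly later in antenna and photosystem genes. Only the jasmonate and antenna lists were set against matched random sets, given further below, which left the question open. Rhythm differences were called in 8 of 10 jasmonate, 14 of 17 starch, 10 of 14 dehydration, 12 of 19 antenna and 10 of 16 photosystem genes. Among all 2398 genes rhythmic at both ages it was 961, and that test also passes for a change of amplitude alone. In 10 jasmonate genes rhythmic at both ages the mean shift was −2.77 ± 0.54 h (SD over replicate numbers, n = 3), with 8 of 10 earlier. Among them were LOX2, the first enzyme of jasmonate synthesis in the chloroplast (−4.75 ± 0.57 h, SE), OPR3 (−3.57 h) and AOC2 (−2.12 h). In 17 starch genes it was −0.82 ± 0.39 h, with 16 earlier, and in 14 abscisic acid and dehydration genes, which include cold-responsive COR15B (−1.29 h), it was −0.97 ± 0.23 h, with 12 earlier. In 19 antenna genes it was 0.81 ± 0.12 h, with 17 later, such as LHCB1.1 (1.31 h) and LHCB6 (1.44 h), and in 16 photosystem genes 0.67 ± 0.46 h, with 15 later, such as PSAK (2.08 h). In 23 clock genes it was −0.19 ± 0.08 h, with 11 earlier and 12 later. CCA1 came 0.83 h earlier and LNK2 1.52 h earlier, and TOC1, an evening factor, came 0.62 h later. The rhythm difference calls of LHCB1.1 and PSAK were lost without replicate 2, and that of TOC1 without replicate 1 and without replicate 2. The mean shifts of lists have no test across genes, and an exact test on 3 replicate numbers cannot reach a p under 0.05.

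The largest advances among the 515 genes with amplitudes of at least 1 at both ages were those of ELIP1 (−4.90 h), LOX2 (−4.75 h), APY5 (−4.43 h), CORI3 (−4.27 h) and CDF2 (−3.93 h). The largest delays were those of ACD6, of defence signalling (4.09 h), the chaperone HSP90.1 (3.37 h), AT5G26690 (2.94 h), RLP34 (2.91 h) and AT1G35710 (2.88 h). Rhythm differences were called for the 5 advances, ACD6 and HSP90.1, and not for AT5G26690, RLP34 and AT1G35710 (adjusted p = 0.272, 0.172 and 0.067). The calls of ACD6 and HSP90.1 were lost without replicate 2, and that of APY5 without replicate 3. Over the 2398 genes rhythmic at both ages the mean shift was −0.06 ± 0.35 h (SD, n = 3), within the spread between replicate numbers. By peak time at 21 DAS it was −0.42 ± 0.27 h at ZT0 to ZT4, 0.17 ± 0.16 h at ZT4 to ZT8, −0.80 ± 0.27 h at ZT8 to ZT12, 0.02 ± 0.55 h at ZT12 to ZT16, 0.53 ± 0.71 h at ZT16 to ZT20 and −0.51 ± 0.22 h at ZT20 to ZT24.

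The share of rhythmic genes peaking in the dark was 43.7% at 21 DAS (2193 of 5016) and 55.96% at 35 DAS (1818 of 3249). Over replicate numbers the difference was 10.7 ± 4.17 percentage points (SD, n = 3), larger than its spread, though 3 replicate numbers cannot reach a p under 0.05 in an exact test. The densest 2-h window was ZT16 to ZT18 at 21 DAS, with 21.7% of peaks, and ZT18 to ZT20 at 35 DAS, with 25.6%. After rescaling it was ZT0 to ZT2 at 21 DAS, with 12.2%, against 9.78% at ZT16 to ZT18, and ZT18 to ZT20 at 35 DAS, with 17.7%. After rescaling the shares were 31.2% and 40.4%. With the boundary at ZT14 they were 59.8% and 60.8%, and 38.6% and 43.1% after rescaling, with the boundary at ZT18 22.1% and 43.1%, and among genes rhythmic at both ages 44.5% and 51.0%, all chosen after the data were seen.

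**Figure D4:**
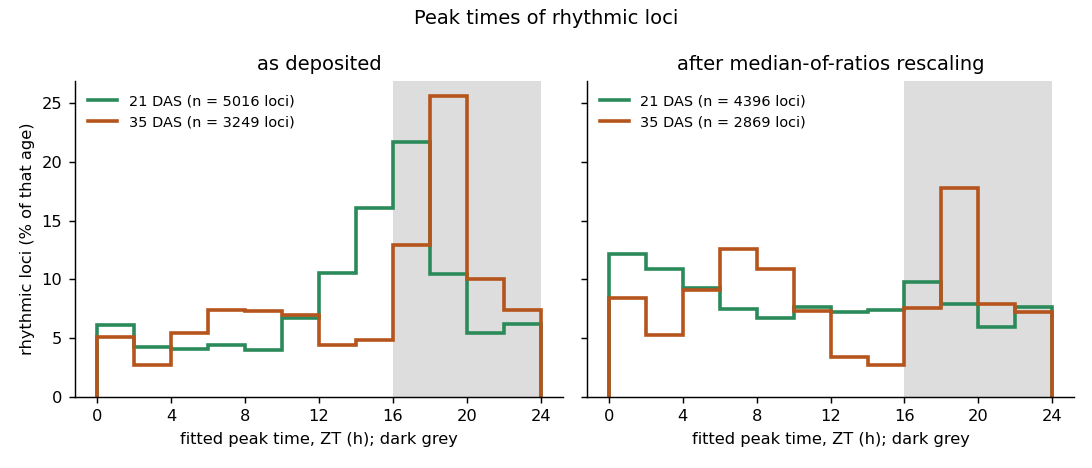
Fitted peak time of rhythmic genes (x axis, ZT in hours, dark in grey) as percent of the rhythmic genes of that age (y axis), as deposited on the left and after rescaling on the right. Lines are 21 DAS (5016 and 4396 genes) and 35 DAS (3249 and 2869 genes). The highest bin at 35 DAS is ZT18 to ZT20 in both panels.

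The night-pattern score averaged over the 6 times was higher at 35 DAS by 0.366 SD units (two-sided permutation test, p = 0.00025), and by 0.240 after rescaling (p = 0.016). A mean over the day leaves out the daily rhythm, so this is a difference in the mean level of the 2 gene sets and not a move of their timing. The median age log2 fold change was 0.57 for genes peaking at ZT16 to ZT20 at 21 DAS, 0.01 at ZT20 to ZT24, −0.38 at ZT4 to ZT8 and 0.45 at ZT8 to ZT12. With ages swapped within replicate pairs the p was 0.0021. By time the difference was 0.151 at ZT1, 0.588 at ZT5, 1.04 at ZT9, 0.480 at ZT13, −0.240 at ZT17 and 0.178 at ZT21. In an exact permutation test at 1 time, 3 libraries against 3 cannot go below 0.1, which was reached at ZT5, ZT9, ZT13 and ZT21. Without replicate 1 the difference was 0.119 (permutation p = 0.25). Genes of the score were chosen at 21 DAS, so part of the daytime difference can follow from that choice, and how much was not measured. With genes rhythmic at 35 DAS the difference averaged over the 6 times was 0.634.

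**Figure D5:**
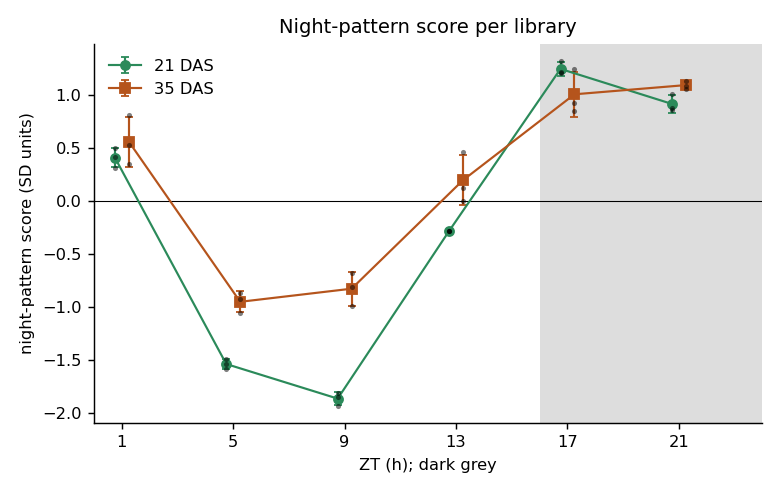
Night-pattern score of each library (y axis, SD units) by time (x axis, ZT in hours, dark in grey). Large points are means with SD of 3 libraries and small points are libraries. The means at ZT9 were −1.86 at 21 DAS and −0.825 at 35 DAS, and at ZT17 they were 1.25 and 1.01.

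The apparent time of day was later at 35 DAS by 0.175 h, which was not called (two-sided permutation test, p = 0.45). Differences at single times went both ways. They were −0.117 h at ZT1, 0.667 h at ZT5, 0.55 h at ZT9, −0.2 h at ZT13, 0.6 h at ZT17 and −0.45 h at ZT21. Libraries of 35 DAS ZT13 read from 11.25 to 14.95 h, against 13 to 13.25 h at 21 DAS, and 1 library of 35 DAS ZT1 read 23.4 h.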

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

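The tests with AT2G01021 at 0, with the boundary at ZT14 and ZT18, with and without rescaling, with rescaling of the dark share and of the ribosomal genes, and of the ribosomal range were chosen only after those results were seen.

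Genes here drew attention because a test of the difference between times or ages passed. The age effect differed between night and day in 2952 genes, and daily rhythm differed between ages in 5073. Night minus day, the age effect was lower for AT5G66053 (−4.94), AT3G28220 (−3.24), BT1 (−3.23), BT2 (−3.19), the nitrate reductase NIA1 (−2.59) and AT4G29905 (−2.47). It was higher for the growth factor PIF4 (2.37), ELIP1 (2.27), STO (1.86), GolS2 (1.78), LNK2 (1.77) and CDF2 (1.76).

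Amplitudes at 35 minus 21 DAS were −1.54 for the pectinesterase PME53, −1.87 for AT1G60590, −1.27 for AT5G23240, −1.41 for NIA1, −0.625 for AT3G01310, −0.63 for BT1, −1.64 for AT1G13650, −0.701 for the isoprenoid enzyme HDR, −1.04 for RUP2, −0.708 for AT5G43440 and −1.38 for AT1G55960. MAP1C differed through its peak time, with an amplitude difference of 0.0391. PME53 and AT1G60590 were near 0 FPKM at 35 DAS, so their lower amplitude is not separate from their fall.

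Most genes were higher at 35 DAS, with a median log2 fold change of 0.39. FPKM share a near-fixed total, so falls of very abundant transcripts could raise all others, and the 200 most abundant genes held 43.1% of FPKM at 21 DAS and 29.7% at 35 DAS. With these 200 left out and the rest rescaled, the median was 0.184, under the bound of 0.2 set for this explanation, against 0.39 for the same genes as deposited. Reads of AT2G01021 are argued against by the lowest median, 0.371, among ZT1, ZT5 and ZT9, where that locus is at 0 in all libraries. A biological rise of many transcripts with age stays open and was not tested, since FPKM carry no absolute scale.

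Rhythmic genes peaked in the dark more often at 35 DAS, by 12.2 percentage points. As deposited, the boundary at ZT16 lies inside the densest group of peaks at 21 DAS, and with a boundary at ZT14 the difference was 0.929 points, and at ZT18 21.0. After rescaling that group is not the densest, and the boundary at ZT14 left 4.46 points (3.94 ± 0.658, SD over replicate numbers, n = 3), so how far the boundary makes the difference stays open. A movement of the whole transcriptome over the day is argued against by 9.13 points after rescaling. A change in which genes pass stays open for part of the difference. Among genes rhythmic at both ages it was 6.55 points, against 12.2 over all rhythmic genes, and above the bound of 1 SD of 4.17. That SD is of the difference over all rhythmic genes, and the spread among genes rhythmic at both ages was not computed. A biological move of peaks around dusk stays open, untested.

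Cytosolic ribosomal protein genes had lower fitted amplitudes at 35 DAS, with a median log2 ratio of −0.836. A lower amplitude of genes in general stays open: 10000 matched random sets had ratios from −0.680 to −0.461 in their middle 95%, but the family was picked after its values were seen and the sets ignore that its members move together. Movement of the whole transcriptome is argued against, as the cause of the lower ratio, by −0.906 after rescaling. The amplitudes themselves fell with rescaling, in the median from 0.541 to 0.368 at 21 DAS and from 0.288 to 0.185 at 35 DAS. A profile that departs from a cosine wave rather than flattening stays open, since the range of the family mean over the 6 times was 1.12 ± 0.189 times that at 21 DAS after rescaling (SD, n = 3), above the bound of 0.8, though 0.872 ± 0.112 as deposited, with 0.788 in replicate 1. A biological change with age was not tested apart from this.

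Other splits of the samples show how often a grouping gives results as large, the real grouping included. For the age effect averaged over the 6 times it was 1 of 100 splits (16433 genes, highest other 13661), and for the amplitude ratio 1 of 100 (0.211, highest other 0.171). For the age effect at night minus day it was 4 of 100 (2952 genes, highest other 11178), and for rhythm differences 2 of 100 (5073 genes, highest other 9362). Splits that mix ages differently at each time turn the age effect into differences between times. Higher counts in other splits can follow from that alone, so the counts at night minus day and for rhythm differences cannot decide. For rhythmic genes at 21 DAS 1 of 100 assignments of times did so (5016, highest other 1807), and for rhythmic genes at 35 DAS 1 of 100 (3249, highest other 1417).

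These splits also mix ages differently at each time. They are therefore no reference without change for results that depend on time, the amplitude ratio included, and those counts are given as values only. Under the bound set beforehand, a grouping by chance stays open for the dark share, the phase shift and both contrasts of the gene lists. For the share of rhythmic genes peaking in the dark 33 of 100 splits were as large (12.2 points, highest other 30.4), and for the phase shift 74 of 100 (0.0955 h, highest other 1.24). For gene lists 32 of 100 called as many (13 lists, highest other 18), and for gene lists at night minus day 82 of 100 (7 lists, highest other 18). The former rest on the age effect averaged over the 6 times. Another split of the ages still called 13661 genes for that effect, so a split can keep part of it. The count for these lists is therefore no reference without change either, and cannot decide. At single times 10 splits are too few to tell. The real split was the 1 with most genes at ZT1 (13195, highest other 1), ZT5 (11891, highest other 0), ZT9 (13086, highest other 1), ZT13 (10798, highest other 207), ZT17 (12062, highest other 35) and ZT21 (13366, highest other 1).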

How the results depend on the processing

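Other dark boundaries, genes rhythmic at both ages and leaving out 5 doubted libraries were chosen only after the data were seen. The estimated correlation was planned with the list test, and only its place among these settings was added afterwards. The age effect averaged over the 6 times kept within 1.5 times its count in 9 of 9 other settings (12264 to 18218 genes) and with each of 36 libraries left out (16314 to 16458). Without a replicate number, which leaves 2 libraries per group, the age effect at night minus day was called in 1165 to 1308 genes and rhythm differences in 1922 to 2673. The averaged age effect was still called in 15624 to 15850 genes. Rhythmic genes numbered 4985 to 5121 at 21 DAS and 3069 to 3547 at 35 DAS. Why the 2 former counts fell more was not tested. With 1 library left out, the age effect at night minus day was called in 2267 to 3375 genes and rhythm differences in 4422 to 6037. Of LHCB7 the age effect lost its call with rescaling, which removes the shift of all genes, and its sign turned, to −0.0602. Rhythm differences rose to 7849 with array weights, and the cause was not tested. With no amplitude minimum, which admits more genes by construction, 14024 and 11984 were rhythmic at 21 and 35 DAS and the amplitude ratio was −0.354, and with rescaling it was −0.284, where the cause was not tested. The dark share differed by 5.60 points by the highest time, 0.929 with the boundary at ZT14 (4.46 with rescaling too), 21.0 at ZT18, 6.55 for genes rhythmic at both ages and 7.96 without the 5 libraries, where the cause was not tested beyond the boundary. The night-pattern score ran from 0.119 to 0.566 without a replicate number, with a permutation p of 0.25 at the lowest, and the cause was not tested. With an estimated correlation camera called 0 of 13 lists for age and 0 of 7 for the gene lists at night minus day, though 9 and 4 had an unadjusted p under 0.05. Of 9495 alternative values for 211 named values, 9465 kept their call, 23 weakened, all without a replicate number, 6 strengthened, all AT1G35710, and 1, that of LHCB7, changed sign. With the replicate number as a block, the age effect averaged over the 6 times was called in 16437 genes, the age effect differs between night and day in 2928, the genes whose rhythm differs between ages number 5064, and all counts stayed within 1.5 times. FPKM carry no counts, so what depth limits in low genes was not measured.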

Other observations

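The gene families below, part of 16 examined, and the library values were chosen after the data were seen, as were the 2 lists of the peak time test. The test itself against matched random sets was written down before its result. Families were matched by words in the gene descriptions, so they can include genes of another kind.

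Expansins, which loosen cell walls, fell in 19 of 20 genes (median −1.85), with EXPA1 at −4.23 ± 0.25 (SE, 18 libraries per age), and arabinogalactan proteins in 28 of 36, with FLA2 at −4.59 ± 0.13. Aquaporins fell in 18 of 23, with PIP1C at −2.79 ± 0.11 and the boron channel NIP5;1 at 1.38 ± 0.12, and tubulins in 12 of 15, with TUB7 at −1.68 ± 0.06. The families were picked after genes such as EXPA8, AGP17 and DELTA-TIP were seen among the largest falls, so no test of a family is given. Chloroplast ribosomal proteins fell in 34 of 36 (median −1.18), with RPL15 at −1.97 ± 0.12, while cytosolic ones were 199 up and 1 down of 217 (median 0.58), and 123 up and 37 down after rescaling (median 0.18). NAC factors rose in 42 of 49 and WRKY factors in 45 of 53, with WRKY26 at 3.82 ± 0.15 and WRKY17 at −1.82 ± 0.12. Proteasome genes were 20 up and 1 down, but 6 up and 7 down after rescaling, and pentatricopeptide repeat genes were 239 up and 62 down, but 88 up and 128 down after rescaling. Genes matched to histones by their descriptions were 16 up and 14 down, but 10 up and 21 down after rescaling.

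Counts of rhythmic genes in families at each age do not by themselves show a difference. Rhythmic cytosolic ribosomal protein genes numbered 133 at 21 DAS and 4 at 35 DAS, and 39 and 1 after rescaling, and 139 differed in rhythm. Rhythmic genes among those matched to histones numbered 25 and 6, and 21 and 4 after rescaling, and 20 of 39 differed in rhythm. Of 13 B-box genes, 12 had a lower amplitude at 35 DAS, with a median of 2.37 and 1.78.

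The hypothesis that jasmonate genes and antenna genes shift in peak time like any genes that peak at the same time was tested, and 2 of 2 lists lay outside the middle 95% of matched random sets. The shift of 10 jasmonate genes was −2.93 h against −1.10 to 0.902 h, and that of 19 antenna genes 0.807 h against −0.440 to 0.678 h. The lists were picked from 16 for their shifts, and random sets ignore that list members move together, so whether these are the shifts of any rhythmic genes with the same peak time at 21 DAS stays open.

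The spread between libraries of a group grew from 0.273 to 1.76 log2 units (SD) for flavonoid and anthocyanin genes, a ratio of 6.47, from 0.103 to 0.406 for Calvin cycle genes, a ratio of 3.93, and by a ratio of 2.72 for salicylic acid and defence genes. For clock genes it went from 0.186 to 0.460, and for all tested genes the ratio was 1.58. The library farthest from its group mean was replicate 2 of ZT13 at 35 DAS, with an SD of deviation of 0.479, followed by replicate 1 of ZT1 at 35 DAS with 0.381. The senescence list mean ran from 2.46 to 3.61 per library at 21 DAS and from 4.52 to 5.99 at 35 DAS.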
